A study of Rattus norvegicus with 16 samples.

How the data were processed

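RNA from the right lung of 16 male Sprague-Dawley rats was hybridised to Affymetrix rat gene arrays, 1 array per rat. Per the labels, the lung vessels were flushed with saline through the pulmonary artery before freezing, RNA was extracted with TRIzol and cleaned on RNeasy columns, every RNA integrity number was at least 9, and the target was labelled with biotin. The rats formed 4 groups of 4: normoxia, hypoxia, hypoxia with estradiol, and hypoxia with estradiol and fulvestrant. Hypoxia was 2 weeks in a chamber at 362 mmHg, equivalent to 10% oxygen at sea level. Estradiol, the main circulating estrogen, came from a pump under the skin at 75 µg/kg/day for 3 weeks, so that it began before the hypoxia. Fulvestrant, an antagonist of both nuclear estrogen receptors, was injected at 3 mg/kg/day. The labels do not say whether the normoxia and hypoxia rats carried pumps without drug.

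The deposited table holds log2 values of RMA, a method that corrects background, normalizes between arrays and summarises the probes of each probe set; the authors made it with RMA and Partek according to their processing notes, which give neither versions nor settings. The log2 scale was checked on the values: array medians lay between 7.69 and 7.77 and no value was missing. RMA aligns the distributions of the arrays, so a shift shared by most genes would not be seen. It also compresses differences of dim probe sets, so folds there may be too small. Arrays carry no count depth, and 4 arrays per group set the precision.

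The table has 29214 probe sets. A gene symbol was found for exactly 1 gene in 15310 of them, 323 had several symbols and 13581 had none. Where a gene had several probe sets the one with the highest overall mean was used (527 genes), which left 14506 genes, of which 14480 had a gene ID in the RefSeq table for rat. The labels name no genome build, so no coordinates are given. No dim genes were left out.

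Groups came from the sample titles. For normoxia replicate 4 the title says normoxia and the treatment field says hypoxia. It was kept as normoxia, since the protocol gives 4 rats per group, and all comparisons that use it were repeated with it counted as hypoxia. Its signature score and first principal component, given below, argue that it was a normoxic lung. Replicate numbers follow the order of submission and pair nothing. No batch, date or chip position is given, and the order of submission follows the groups, so a batch effect between groups could not be told apart from the treatment.

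Differences were tested in R 4.3.3 with limma 3.58.1, in 1 linear model with 4 group means over all 16 arrays and empirical Bayes moderation. Adjusted p values are Benjamini-Hochberg values over all genes, with a threshold of 0.05, and standard errors (SE) are from the moderated fit. The main comparisons were hypoxia against normoxia, hypoxia with estradiol against hypoxia, and hypoxia with estradiol and fulvestrant against hypoxia with estradiol. The 3 other pairs of groups were secondary. Fixed gene lists, 47 of them with at least 7 measured members, were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists. Each was also tested with an estimated correlation, on ranks, and with fry, which asks whether the members of a list move on balance 1 way. A call "adjusted over the list alone" uses Benjamini-Hochberg values over the members of 1 list. In every main comparison 0 lists passed camera with an estimated correlation.

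A hypoxia signature score was the mean, over the 200 genes with the highest and the 200 with the lowest moderated statistic of hypoxia against normoxia, of the signed log2 difference from the normoxia mean. For a hypoxia or normoxia array it was built without that array. Score differences were tested with 2-sided exact permutation tests over 70 splits, for which the smallest possible p is 0.0286.

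The rule for named genes took, per main comparison, the 10 highest and 10 lowest changes among passing genes whose arrays did not overlap between the groups. Placeholder symbols were skipped, and where fewer than 5 passed in a direction the genes with the smallest p filled up to 5. From lists that were called, or had at least 3 passing members, it took up to 4 passing members with the largest changes. It always took Esr1, Esr2, Gper1, Vegfa, Edn1 and Bmpr2, and it took up to 10 genes called in opposite directions in consecutive comparisons. Every gene this rule selects is named. The groups, the tests described above, the gene lists, this rule and the alternatives below, bar 1, were chosen before the data were examined. Some further tests and simulations were chosen after results had been seen, which is said where they appear. Genes named outside the rule, for a small count or for a test in the closing section, are marked where they appear.

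Alternatives were centring each array on its median, quantile normalization applied again, leaving out the dimmest genes, averaging a gene's probe sets, testing all probe sets, an intensity trend in the prior, array weights, an ordinary contrast without moderation, a model of the compared groups alone, other thresholds, signature sizes of 50 and 500 genes each way, other list tests, the other label of normoxia replicate 4, and leaving out each array in turn. Leaving out estradiol replicates 2 and 3 together was added after the data were seen.

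The model was tested on simulated data with changes added to 67, 67 and 66 genes per comparison. Their noise was normal, with each gene's own spread, and independent between genes. It recovered 74.6% to 80.6% of changes of log2 0.50, 97.0% to 100% of log2 1.00 and 100% of log2 2.00, and 3.16% to 5.13% of its calls were false. It called 3 of 3 moved lists and 0 unmoved ones. Since this noise was independent between genes, the 0 does not show how often camera calls unmoved lists of correlated genes. In 100 simulations of unchanged groups from permuted residual arrays, camera called a mean of 13.8 lists for estradiol against hypoxia. The range for a test of shared arrays was drawn from 1000 simulations. This number was raised from 40 to 100 and then to 1000 after the results had been seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.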

Results

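Gene expression was measured in the lungs of 16 male rats, 4 per group, by array. The series title asks whether estrogen receptors mediate a lessening by estradiol of the changes that hypoxia causes in the lung of rats with pulmonary hypertension. Values are log2 RMA signals of 14506 genes. The Pearson correlation across genes between any pair of arrays was between 0.985 and 0.996, and the median SD of a gene within a group was 0.107 in normoxia, 0.115 in hypoxia, 0.129 in hypoxia with estradiol and 0.0917 with fulvestrant added. The first principal component held 22.1% of the variance and separated the normoxia arrays (-20.8 to -12.0) from the rest (-2.05 to 16.3). The second, with 17.4%, set estradiol replicates 2 (-25.4) and 3 (-22.3) apart from the other 14 arrays (-5.18 to 7.85).

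Hypoxia against normoxia asks what chronic low oxygen changed. Ntrk2, the receptor for brain-derived neurotrophic factor (probe set 10797089), rose 12.4-fold, from a log2 value of 7.64 ± 0.44 to 11.28 ± 0.20 (SD, n = 4), a change of 3.63 (SE 0.16, adjusted p = 3.61e-09). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor (probe set 10910376), was 23.0-fold lower, from 10.52 ± 0.32 in normoxia (SD, n = 4; log2 change -4.53, SE 0.58, adjusted p = 0.000285). Lyve1, the hyaluronan receptor of lymphatic endothelium and some macrophages, was 4.70-fold lower (log2 -2.23, SE 0.12, adjusted p = 3.45e-08), and Lypd1 rose 4.47-fold (log2 2.16, SE 0.14, adjusted p = 1.41e-07). In all, 817 genes passed, 465 higher and 352 lower (431 and 447 with quantile normalization again, 425 and 394 with median centring, 484 and 488 over all probe sets), and 280 of them differed at least 1.5-fold.

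Other large increases were Or51e1, an olfactory receptor gene expressed outside the nose (log2 2.04), Mgarp (2.01), Rbp7, a retinol-binding protein (1.95), Slc26a10 (1.91), Amd1, an enzyme of polyamine synthesis (1.84), the kininogen gene Kng2 (1.81), the BMP antagonist Grem1 (1.71) and Serpina3n, an acute-phase serpin (2.54). Large decreases were Abcb1b, a drug efflux pump (log2 -2.03), the natriuretic peptide clearance receptor Npr3 (-1.84), the prostaglandin-degrading enzyme Hpgd (-1.66), the receptor for vasoactive intestinal peptide Vipr1 (-1.62), Lypd8l1 (-1.20) and Pdia5 (-1.13). For these 14 genes adjusted p ran from 8.04e-08 (Slc26a10) to 0.0421 (Serpina3n), and the 4 arrays of each group did not overlap.

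**Figure D1:**
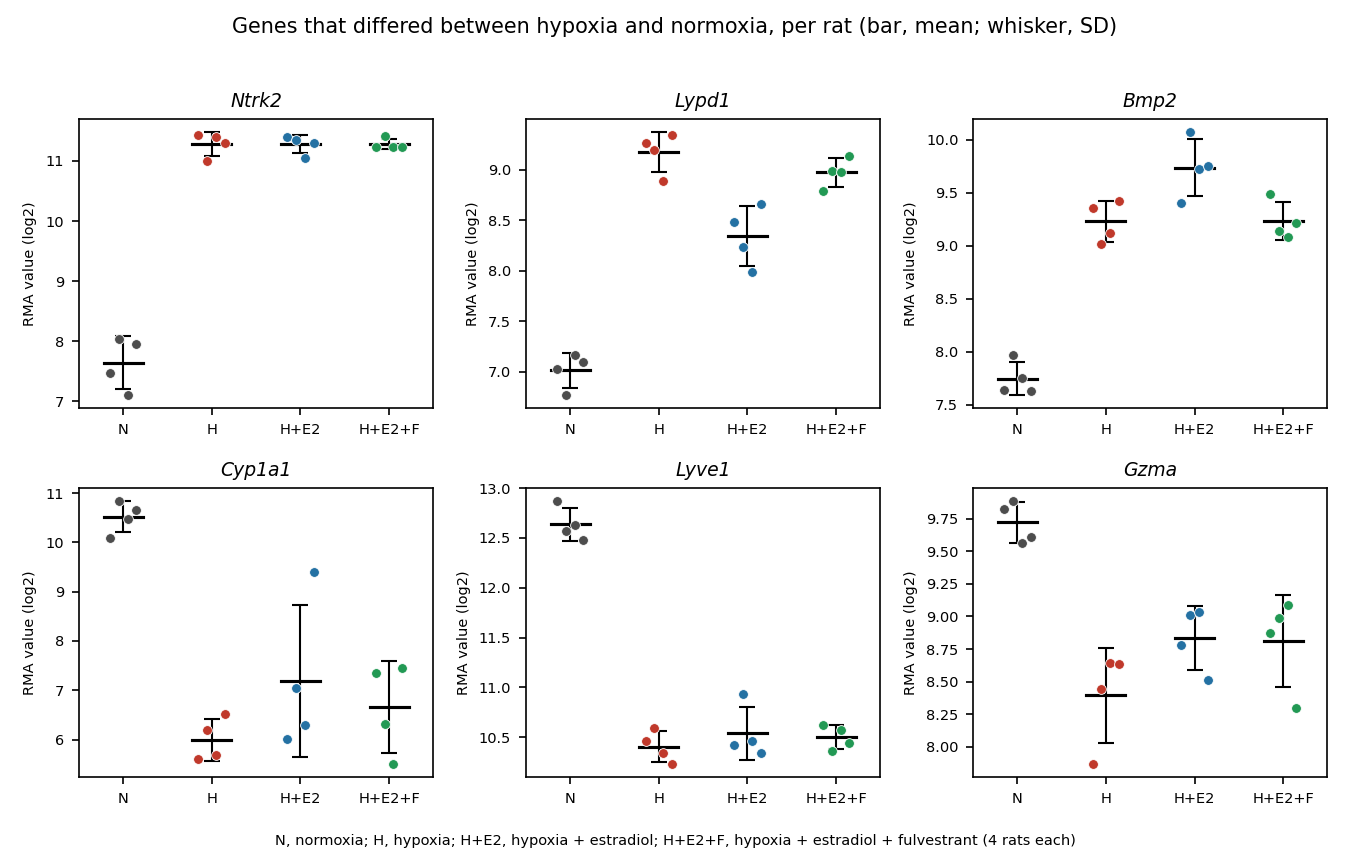
RMA log2 value (vertical axis) of 6 genes in each rat by group (horizontal axis); points are rats, bars are means and whiskers are SD (n = 4). Ntrk2 means were 7.64 in normoxia and 11.28 in hypoxia, and Cyp1a1 differed by -4.53 from a normoxia mean of 10.52.

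The lists of glycolysis and of the response to low oxygen were called higher, with a minority of their genes past. Of 19 glycolysis genes 8 rose, 0 fell and 11 did not pass (11 and 0 adjusted over the list alone, median log2 0.22, camera adjusted p = 4.74e-08, and adjusted p = 0.28 with an estimated correlation). They included Aldoc (log2 1.10), the lactate exporter Slc16a3 (0.90), Tpi1 (0.88) and Pfkl (0.66). Aldoc, Tpi1 and other glycolysis genes are also members of the next list, so these lists are not independent. Of 37 targets of hypoxia-inducible factors 11 rose, 1 fell and 25 did not pass (15 and 2 adjusted over the list alone, median 0.19, camera adjusted p = 0.000235, and adjusted p = 0.28 with an estimated correlation), among them the mitophagy gene Bnip3 (0.72) and Hmox1 (0.87), which breaks down haem. Vegfa (-0.10, adjusted p = 0.421) and Edn1 (0.67, SE 0.37, adjusted p = 0.329), both classical targets of this pathway, did not pass.

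The lists of matrix, smooth muscle and pericyte genes were called higher, with less than a majority of their genes past. Of 35 extracellular matrix genes 11 rose, 1 fell and 23 did not pass (15 and 1 adjusted over the list alone, median log2 0.32, camera adjusted p = 9.27e-08, and adjusted p = 0.509 with an estimated correlation). Examples were Ccn2 (0.82), Plod2, which hydroxylates collagen lysines (0.80), Ltbp2 (0.73) and the crosslinking enzyme Loxl1 (0.66). Of 19 genes of the contractile apparatus of smooth muscle 6 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.23, camera adjusted p = 9.51e-06, and adjusted p = 0.509 with an estimated correlation), with Des at 0.75, Cnn1 at 0.62, Smtn at 0.60 and Tpm2 at 0.52. Of 11 pericyte markers 3 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.00198, and adjusted p = 0.53 with an estimated correlation): Trpc6 (0.66), Cspg4 (0.42) and Pdgfrb (0.28). The mitosis list was called higher although 0 of its 29 genes passed, adjusted over all genes or over the list alone (median 0.28, camera adjusted p = 0.000149, and adjusted p = 0.72 with an estimated correlation), a call lost with normoxia replicate 4 counted as hypoxia (adjusted p = 0.223).

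Signalling and vascular genes moved in both directions. In the list of BMP and TGF-beta signalling, which was not called (camera adjusted p = 0.498), 5 of 37 genes rose and 3 fell (5 and 5 adjusted over the list alone). Risers were Grem1, Bmp2 (log2 1.48, SE 0.13, adjusted p = 1.12e-05), the activin subunit Inhba (1.99-fold) and Tgfb3 (0.77). Bmpr2, the receptor mutated in heritable pulmonary arterial hypertension, changed by -0.21 (SE 0.06, adjusted p = 0.0562). Of 42 genes of pulmonary vascular tone 7 rose and 2 fell (13 and 4 adjusted over the list alone, median 0.15, camera adjusted p = 0.0498, and adjusted p = 0.569 with an estimated correlation). The serotonin transporter Slc6a4 fell (-0.97), and Agt, the precursor of angiotensin (0.77), Trpc6 and the arginase Arg1 (0.66) rose. This list lost its call without normoxia replicate 3 (adjusted p = 0.0676) or 4 (0.0741) and without hypoxia replicate 1 (0.0712) or 3 (0.123).

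Among 15 endothelial markers 3 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.726): Robo4 (log2 0.80), Egfl7 (0.73) and Emcn (0.69) were higher and Clec14a (-0.60) lower. Among 13 markers of lung capillary endothelium 3 rose and 4 fell (3 and 5 adjusted over the list alone, median -0.04, camera adjusted p = 0.0262, lower, and adjusted p = 0.509 with an estimated correlation). Hpgd and Plvap, a component of endothelial diaphragms (-0.83), fell, and Scn7a (0.89) and Gpihbp1, which anchors lipoprotein lipase (0.86), rose. The call was lost without normoxia replicate 1 (adjusted p = 0.0526) or 2 (0.0847). In the lymphatic list, which was not called (camera adjusted p = 0.42), 3 of 7 rose and 1 fell (3 and 1 adjusted over the list alone): the chemokine Ccl21 (1.09), Reln (0.56) and Prox1 (0.48) rose, while Lyve1 fell. The list of estrogen receptors, metabolism and response was not called (camera adjusted p = 0.451), with 2 of 25 genes higher and 1 lower (3 and 2 adjusted over the list alone): the nitric oxide synthase Nos3 (0.59), Ramp3 (0.59) and Cyp1a1. The receptor genes Esr1 (-0.41, SE 0.13, adjusted p = 0.0864), Esr2 (0.05, adjusted p = 0.889) and Gper1 (0.02, adjusted p = 0.952) did not pass.

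The 3 lists of lymphocyte markers were called lower in hypoxia. Of 18 genes of natural killer and cytotoxic cells 12 fell and 0 rose (13 and 0 adjusted over the list alone, median log2 -0.72, camera adjusted p = 1.83e-15, and adjusted p = 0.168 with an estimated correlation), among them the granzymes Gzma (-1.32) and Gzmk (-1.11) and the receptors Klri2 (-1.27) and Klrd1 (-1.04). Of 22 T cell markers 12 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.59, camera adjusted p = 6.04e-14, and adjusted p = 0.28 with an estimated correlation), such as Il7r (-0.78), Trat1 (-0.75), Ccr7 (-0.72) and Cd3d (-0.69). Of 14 B cell markers 2 fell, Cd22 (-0.81) and Pou2af1 (-0.51), and 0 rose (5 lower and 1 higher adjusted over the list alone, median -0.38, camera adjusted p = 8.46e-06, and adjusted p = 0.509 with an estimated correlation).

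The macrophage, cytokine and erythrocyte lists were called higher, although most of their genes did not pass. Of 16 alveolar macrophage markers 6 rose and 0 fell (8 and 0 adjusted over the list alone, median log2 0.61, camera adjusted p = 1.61e-05, and adjusted p = 0.28 with an estimated correlation), with Ctsk (0.98), Gpnmb (0.90), Fabp4 (0.88) and Chi3l1 (0.79) as examples. Of 19 markers of monocytes and interstitial macrophages 4 rose and 0 fell (5 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.0401, and adjusted p = 0.72 with an estimated correlation): the complement genes C1qc (0.67), C1qb (0.66) and C1qa (0.60) and the folate receptor Folr2 (0.63). That call was lost without normoxia replicate 4 (adjusted p = 0.0789) or hypoxia replicate 4 (0.255). Of 35 cytokines and chemokines 5 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.00492, and adjusted p = 0.603 with an estimated correlation), led by the monocyte attractant Ccl2 (1.48), Cxcl13 (1.19), Cxcl6 (0.89) and Cxcl12 (0.75). Of 13 erythrocyte markers 1 rose, Hemgn (1.27), and 0 fell (10 and 0 adjusted over the list alone, median 1.27, camera adjusted p = 1.61e-05, and adjusted p = 0.509 with an estimated correlation); the list mean above normoxia was 1.40, 1.23, -0.06 and 1.31 in the 4 hypoxia arrays.

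In lists that were not called, 3 of 19 glucocorticoid-responsive genes rose (4 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.362): Lcn2 (log2 1.26), the metallothionein Mt1 (0.94) and Sgk1 (0.81). Of 33 antioxidant genes 3 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.448): Hmox1, Gpx8 (0.47) and Gpx4 (0.33). Of 15 markers of alveolar type 1 cells, a list called lower, 1 fell, Hopx (-0.22), and 0 rose (1 and 0 adjusted over the list alone, median -0.07, camera adjusted p = 0.0387, and adjusted p = 0.603 with an estimated correlation). That call was lost without normoxia replicate 1 (0.0526), 2 (0.074) or 3 (0.153) and without hypoxia replicate 1 (0.0763) or 2 (0.0536).

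Of the 817 calls, 372 were made in each of the 8 fits that left out 1 array of either group. The count was 428 without normoxia replicate 1, 541 without replicate 2, 442 without hypoxia replicate 1, 515 without hypoxia replicate 2 and 40 with normoxia replicate 4 counted as hypoxia. Of the 86 named genes that passed, 63 were called in all 8 fits. The other 23 were lost in at least 1 fit each, 23 without normoxia replicate 1, 16 without 2, 8 without 3 and 13 without 4, and 20 without hypoxia replicate 1, 18 without 2, 3 without 3 and 14 without 4. These were Serpina3n, Hemgn, Lcn2, Cxcl13, Mt1, Gpnmb, Fabp4, Hmox1, Cd22, Chi3l1, Agt, Trat1, Cd3d, Folr2, Ramp3, Tpm2, Pou2af1, Prox1, Gpx8, Gpx4, Pdgfrb, Hopx and Srpx. Serpina3n, for example, had an adjusted p of 0.127 without hypoxia replicate 2. All 86 kept their sign, which genes that passed in these same arrays could hardly fail to do. The largest move was 1.41-fold (Serpina3n, to log2 3.04 without hypoxia replicate 4).

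Hypoxia with estradiol against hypoxia asks what estradiol changed while oxygen was low. Neutrophil genes made up much of the top of the list: the collagenase Mmp8 rose 3.85-fold (log2 1.94, SE 0.36), the calprotectin subunits S100a8 3.35-fold (1.74, SE 0.27) and S100a9 3.05-fold (1.61, SE 0.31), and Retnlg 3.33-fold (1.73, SE 0.35), each with adjusted p between 0.0295 and 0.0362. Lypd8l1 rose 3.01-fold, from 7.83 ± 0.18 to 9.42 ± 0.27 (SD, n = 4; log2 1.59, SE 0.21, adjusted p = 0.00848). Grem1 was 2.16-fold lower, at 6.87 ± 0.23 against 7.98 ± 0.09 (log2 -1.11, SE 0.14, adjusted p = 0.00848), Or51e1 was 2.70-fold lower (-1.43, SE 0.28) and the Wnt modulator Sfrp2 was 2.63-fold lower (-1.40, SE 0.27). In all, 112 genes passed, 45 higher and 67 lower, and 44 differed at least 1.5-fold.

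The other large increases were the IgA receptor Fcar (log2 1.82), the chemokine receptor Cxcr2 (1.48), the lectin Clec4d (1.45), the clock gene Per1 (1.31) and the receptor for granulocyte colony-stimulating factor Csf3r (1.27). The other large decreases were the Notch target Hey2 (-0.99), Scara3 (-0.93), Fam151a (-0.92), Cxcl6 (-0.90), Srpx (-0.90), Prnd (-0.85) and Lypd1 (-0.83). Of 19 neutrophil markers 6 rose and 0 fell (12 higher and 1 lower adjusted over the list alone, median 1.11, camera adjusted p = 3.35e-11, and adjusted p = 0.324 with an estimated correlation). The list mean above normoxia was 0.42, 1.13, 0.70 and 0.29 in estradiol replicates 1 to 4 and at most 0.08 in the hypoxia arrays.

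The glucocorticoid, clock and immediate early lists were called higher with estradiol, although few or none of their genes passed. Of 19 glucocorticoid-responsive genes 3 rose, Per1, the anti-inflammatory Tsc22d3 (log2 0.90) and the transcription factor Klf9 (0.71), and 0 fell (10 and 2 adjusted over the list alone, median 0.51, camera adjusted p = 2.09e-06, and adjusted p = 0.324 with an estimated correlation). Of 17 clock genes 1 rose, Per1, which is in both lists, and 0 fell (5 and 0 adjusted over the list alone, median 0.37, camera adjusted p = 0.000227, and adjusted p = 0.324 with an estimated correlation). The immediate early list was called although 0 of 28 genes passed (1 higher adjusted over the list alone, median 0.38, camera adjusted p = 6.59e-08, and adjusted p = 0.66 with an estimated correlation). Its mean above normoxia was 1.31 and 0.70 in estradiol replicates 2 and 3, the arrays apart on the second component, and 0.27 and 0.26 in replicates 1 and 4. Without replicates 2 and 3 the immediate early call ended (median 0.04, adjusted p = 0.381).

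Lists of matrix and vessel genes were called lower, with at most 2 genes of each past. Of 35 matrix genes 2 fell, Mfap5 (log2 -0.65) and Loxl1 (-0.55), and 0 rose (8 and 0 adjusted over the list alone, median -0.23, camera adjusted p = 1.5e-05, and adjusted p = 0.685 with an estimated correlation). Of 13 capillary markers 2 fell, the peptide ligand Apln (-0.81) and the carbonic anhydrase Car4 (-0.33), and 0 rose (6 and 0 adjusted over the list alone, median -0.16, camera adjusted p = 0.00322, and adjusted p = 0.512 with an estimated correlation). Of 11 pericyte markers 2 fell, Rgs5 (-0.76) and Pdgfrb (-0.35), and 0 rose (2 and 0 adjusted over the list alone, median -0.14, camera adjusted p = 0.00976, and adjusted p = 0.714 with an estimated correlation). The pericyte call was lost without hypoxia replicate 1 (0.0538) or estradiol replicate 3 (0.143). In BMP and TGF-beta signalling, not called (camera adjusted p = 0.121), Grem1, Inhba (-0.52) and Tgfb2 (-0.49) fell and 0 of 37 rose (4 lower and 1 higher adjusted over the list alone). Of 15 endothelial markers 1 fell, Robo4 (-0.39), and 0 rose (3 and 0 adjusted over the list alone, median -0.07, camera adjusted p = 0.0321, and adjusted p = 0.8 with an estimated correlation), a call lost without hypoxia replicate 3 (0.241) or estradiol replicate 3 (0.421). Of 42 genes of vascular tone 1 fell, Apln, and 0 rose (2 and 0 adjusted over the list alone, median -0.08, camera adjusted p = 0.00976, and adjusted p = 0.544 with an estimated correlation), a call lost without estradiol replicate 3 (0.0522).

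T cell and natural killer lists were called higher than in hypoxia, and the B cell list was not called. Of 22 T cell markers 1 rose, Il7r (log2 0.90), and 0 fell (1 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 9.25e-05, and adjusted p = 0.714 with an estimated correlation). Of 18 natural killer markers 0 passed (3 higher and 0 lower adjusted over the list alone, median 0.27, camera adjusted p = 9.25e-05, and adjusted p = 0.569 with an estimated correlation). Both calls were lost with normoxia replicate 4 counted as hypoxia (adjusted p = 0.246 and 0.123). Of 14 B cell markers 1 fell and 0 rose (1 lower and 0 higher adjusted over the list alone, median 0.07, camera adjusted p = 0.65), and their mean relative to normoxia was -0.45 in hypoxia and -0.42 with estradiol. Without estradiol replicates 2 and 3 the B cell median was -0.08 (adjusted p = 0.223). Erythrocyte markers were lower as a list with 0 of 13 genes past, also over the list alone (median -0.44, camera adjusted p = 0.00976, and adjusted p = 0.798 with an estimated correlation), a call lost without hypoxia replicate 1 (0.0532) or estradiol replicate 3 (0.102). Esr1 (-0.10, adjusted p = 0.763), Esr2 (-0.10, 0.77), Gper1 (0.00, 0.999), Vegfa (-0.12, 0.37), Edn1 (-0.04, 0.968) and Bmpr2 (0.02, 0.891) did not pass, and neither did any of the 25 genes of estrogen receptors, metabolism and response (1 higher and 1 lower adjusted over the list alone, and fry adjusted p = 0.785).

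**Figure D2:**
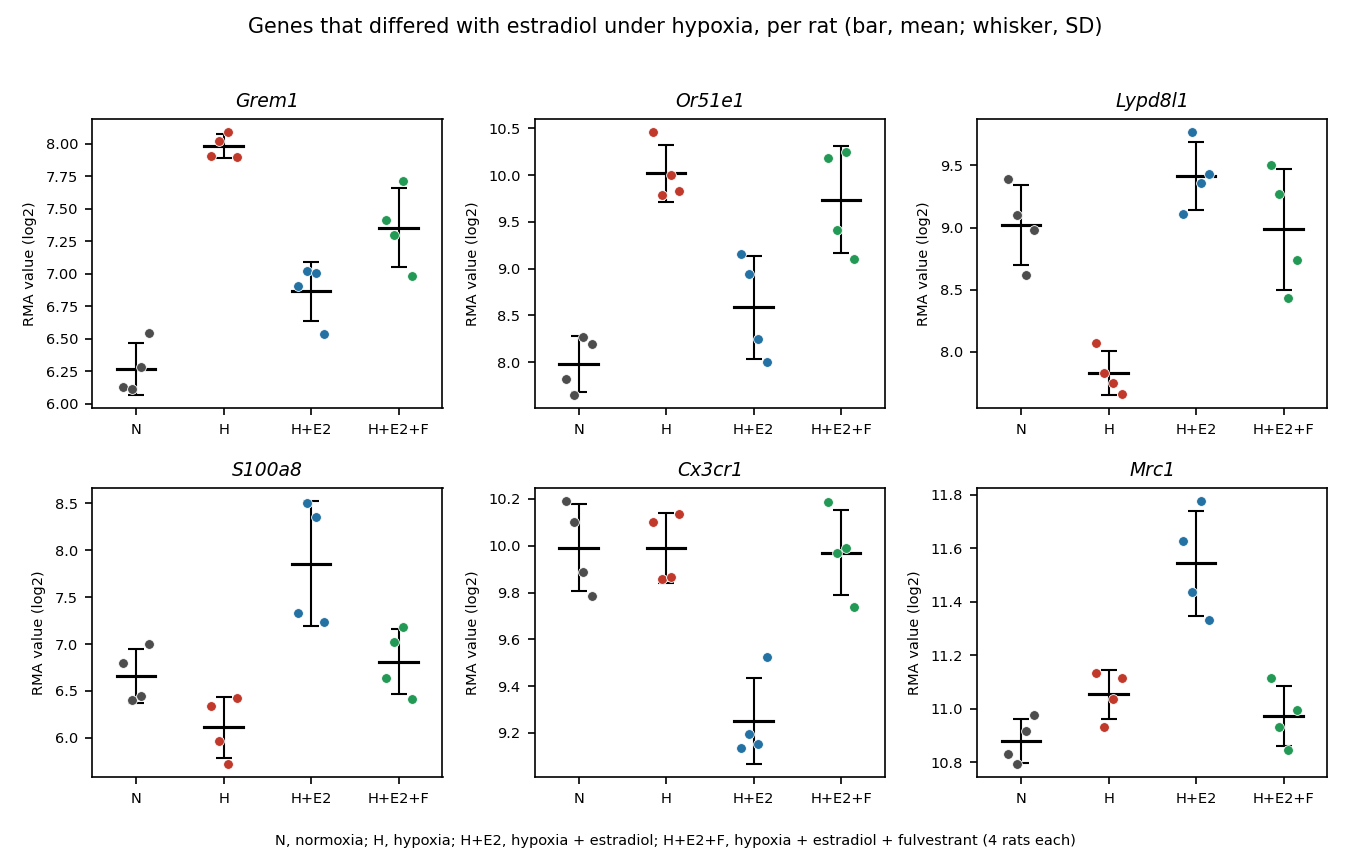
RMA log2 value (vertical axis) of 6 genes in each rat by group (horizontal axis); points are rats, bars are means and whiskers are SD (n = 4). Grem1 means were 6.27 in normoxia, 7.98 in hypoxia and 6.87 with estradiol.

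The number of genes called with estradiol rested on single arrays. It was 7, 3 and 5 without hypoxia replicates 1, 2 and 4, 4 without estradiol replicate 2, 4 without estradiol replicate 3, 219 without estradiol replicate 1 and 355 without estradiol replicate 4. Only Gask1b, Grem1 and Lypd8l1 were called in all 8 such fits (Gask1b, outside the rule, is named because the count is small). Of the 37 named genes that passed, 35 lost the call in at least 1 fit, 34, 35, 17 and 33 without hypoxia replicates 1 to 4 and 3, 35, 35 and 2 without estradiol replicates 1 to 4. All 37 kept their sign in these fits, which again could hardly fail. The largest move without 1 array was 1.28-fold (Fcar, to log2 1.46 without estradiol replicate 3), so these calls were lost with changes of similar size. Without estradiol replicates 2 and 3 together limma called 0 genes (1335 at an unadjusted p under 0.05). All 112 genes kept their sign, which was likely since the remaining arrays had helped to select them. Some neutrophil genes then had smaller changes, with Fcar at log2 1.18, Cxcr2 at 0.89 and Clec4d at 0.80. Grem1 (-1.26) and Or51e1 (-1.44) did not shrink. The neutrophil median was then 0.47 and the glucocorticoid median 0.17, and the calls of the pericyte (0.226), endothelial (0.503), vascular tone (0.121), erythrocyte (0.444), interferon (0.527), immediate early (0.381) and actin filament (0.226) lists ended. The count of called genes was also 0 with normoxia replicate 4 counted as hypoxia, 4 with array weights and 5 in a model of these 8 arrays alone. Leaving out estradiol replicate 1 ended the call of the heat shock list (camera adjusted p = 0.26). The actin filament call was lost without hypoxia replicate 1 (0.0959) or 2 (0.0599). It was also lost without estradiol replicate 1 (0.0534), 2 (0.112) or 3 (0.0527).

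**Figure D3:**
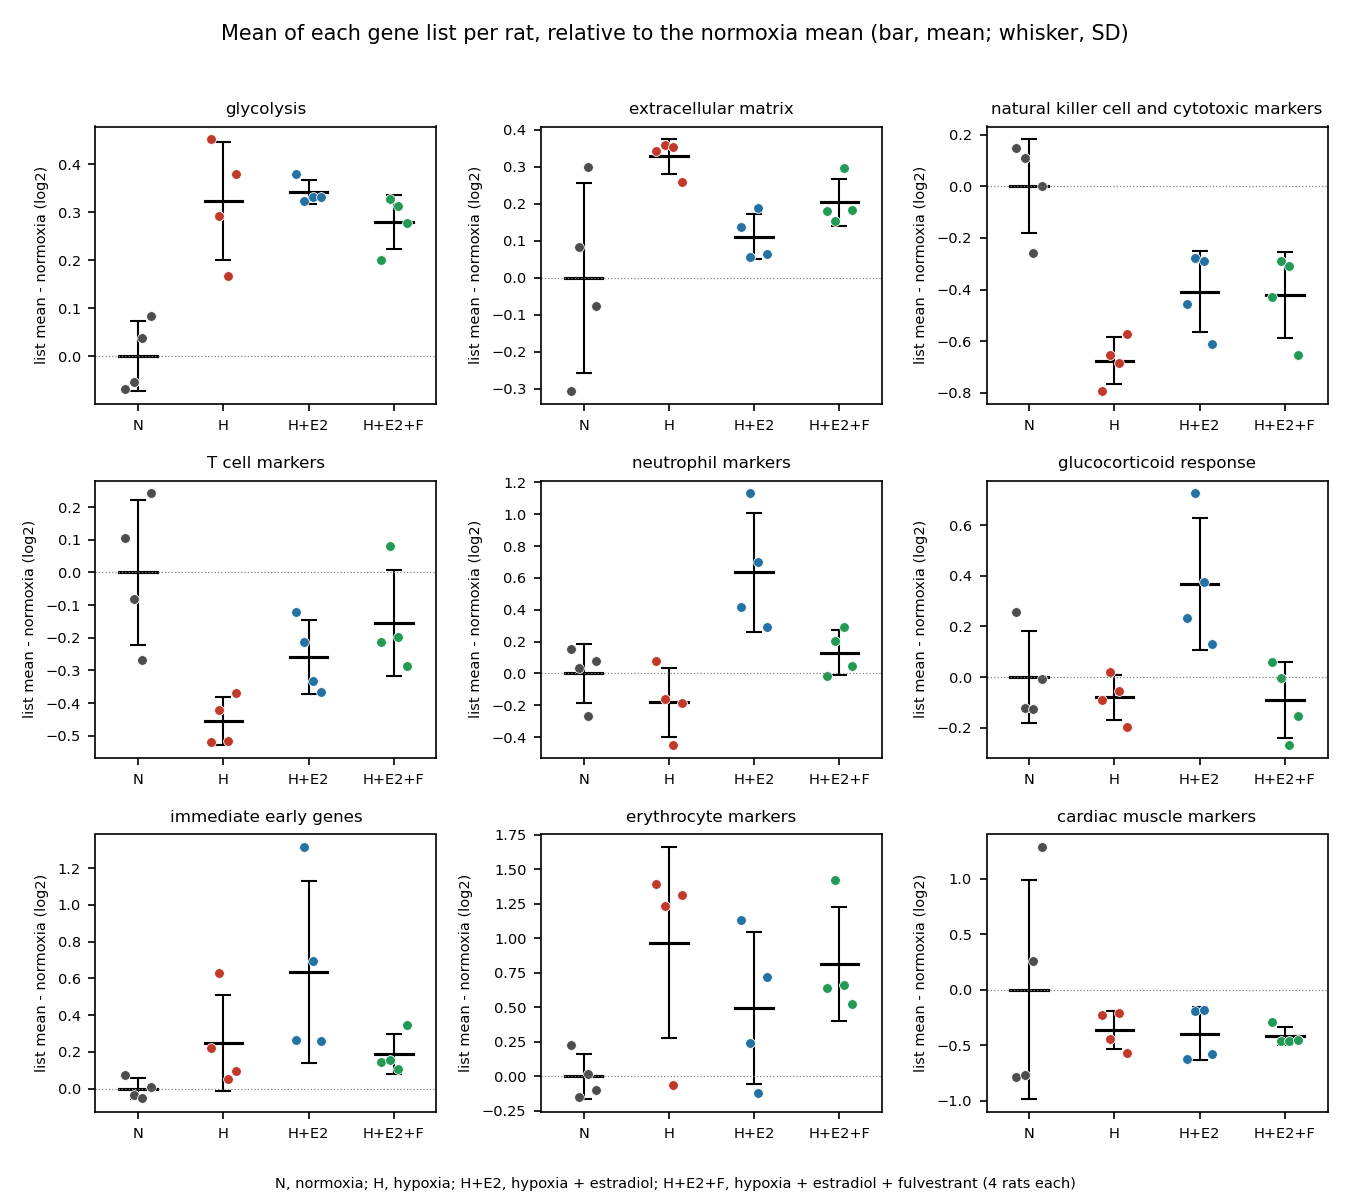
Mean log2 difference from the normoxia mean (vertical axis) of 9 gene lists in each rat by group (horizontal axis); points are rats, bars are means and whiskers are SD (n = 4). Neutrophil means in the estradiol rats were 0.42, 1.13, 0.70 and 0.29, and natural killer means averaged -0.68 in hypoxia.

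Hypoxia with estradiol and fulvestrant against hypoxia with estradiol asks what changed when fulvestrant was added. No group had fulvestrant without estradiol. An effect of fulvestrant itself, or of its injection, therefore cannot be told apart from an undoing of the effect of estradiol. The fractalkine receptor Cx3cr1, a monocyte gene, rose 1.65-fold, from 9.25 ± 0.19 to 9.97 ± 0.18 (SD, n = 4; log2 0.72, SE 0.12, adjusted p = 0.0403). Septin4 (0.49, adjusted p = 0.0495) and the cytokine receptor Il17rb (0.49, adjusted p = 0.0403) also rose. The motor protein Myo5b was 1.38-fold lower (-0.46, SE 0.06, adjusted p = 0.0142), the macrophage mannose receptor Mrc1 1.48-fold lower (-0.57, SE 0.09, adjusted p = 0.0403), and Megf6 (-0.55) and the kinase Prkx (-0.36) were lower. These 7 genes, 3 higher and 4 lower, were all that passed, with 2142 at an unadjusted p under 0.05. Rgs5 (0.75), Atp1b2 (0.65) and the phosphodiesterase Pde4c (-0.69) did not pass (adjusted p = 0.0586 each). Esr1 (0.19, adjusted p = 0.56), Esr2 (-0.10, 0.815), Gper1 (0.22, 0.35), Vegfa (0.15, 0.29), Edn1 (0.05, 0.974) and Bmpr2 (-0.01, 0.965) did not pass. Another, dimmer probe set of Esr1 (10702695), not used above, had larger changes in the same directions. They were 0.41 with fulvestrant, -0.235 with estradiol and -0.44 in hypoxia.

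Of the 15 lists called with estradiol, 10 were called in the opposite direction with fulvestrant, 1 in the same direction and 4 not at all. In addition, 7 other lists were called when fulvestrant was added and not with estradiol. The neutrophil list was lower with 0 of 19 genes past (8 lower and 0 higher adjusted over the list alone, median log2 -0.44, camera adjusted p = 4.76e-06, and adjusted p = 0.465 with an estimated correlation). The glucocorticoid list was lower with 0 of 19 past (8 and 0 adjusted over the list alone, median -0.54, camera adjusted p = 4.76e-06, and adjusted p = 0.386 with an estimated correlation). So were the clock list (0 of 17 past; 7 lower and 1 higher adjusted over the list alone, median -0.42, camera adjusted p = 0.00033, and adjusted p = 0.383 with an estimated correlation) and the immediate early list (0 of 28 past, also over the list alone, median -0.38, camera adjusted p = 8.37e-09, and adjusted p = 0.597 with an estimated correlation). Without estradiol replicates 2 and 3 the immediate early call ended (adjusted p = 0.101). The neutrophil list then had a median of -0.18 with 0 lower over the list alone (camera adjusted p = 0.0317, and adjusted p = 0.815 with an estimated correlation), the glucocorticoid list -0.15 with 1 lower (0.00987, and 0.644 with an estimated correlation), and the clock list -0.45 with 5 lower and 2 higher (0.017, and 0.644). Higher were capillary markers (0 of 13 past; 5 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.000122, and adjusted p = 0.383 with an estimated correlation) and matrix genes (0 of 35 past; 2 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.00569, and adjusted p = 0.699 with an estimated correlation). The other 4 of the 10 were vascular tone (median 0.10, camera adjusted p = 0.00569), pericyte markers (0.08, 0.00888), endothelial markers (0.11, 0.0135) and heat shock genes (-0.08, 0.00888), with adjusted p = 0.465, 0.694, 0.694 and 0.694 with an estimated correlation. None of their genes passed in limma, and adjusted over the list alone 3, 3, 4 and 0 were higher and 0, 0, 1 and 1 lower. The pericyte (0.175) and endothelial (0.246) calls were lost without estradiol replicate 3, and also without replicates 2 and 3 together (0.285 and 0.409), and the heat shock call without estradiol replicate 1 (0.228) or fulvestrant replicate 2 (0.0717). These comparisons share the estradiol arrays, which by itself turns lists around. In 100 simulations of unchanged groups, set after the counts had been seen, 40.5% of the lists called with estradiol were called opposite with fulvestrant, against the real 66.7%, and 10 of the simulations had 10 or more such lists. The count of 10 thus does not exclude the shared arrays as its cause.

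The other 5 lists called with estradiol were not called in the opposite direction. T cell markers were called higher again with fulvestrant (0 of 22 past; 2 higher and 0 lower adjusted over the list alone, median log2 0.12, camera adjusted p = 0.0451, and adjusted p = 0.862 with an estimated correlation). Their mean relative to normoxia was -0.46 in hypoxia, -0.26 with estradiol and -0.15 with fulvestrant added, and the call was lost without estradiol replicate 3 (0.094) or 4 (0.301) or fulvestrant replicate 2 (0.592), without estradiol replicates 2 and 3 (0.053) and with quantile normalization again (0.0685). Natural killer markers were not called with fulvestrant (camera adjusted p = 0.864), nor were the erythrocyte, interferon and actin filament lists, and the interferon mean was 0.29, 0.06 and -0.04 in these groups. Of the 7 lists called when fulvestrant was added and not with estradiol, smooth muscle genes were higher (0 of 19 past, with 10 higher and 0 lower adjusted over the list alone, median 0.21, camera adjusted p = 1.37e-07, and adjusted p = 0.465 with an estimated correlation). Their mean relative to normoxia was 0.30 in hypoxia (0.17 to 0.44), 0.18 with estradiol and 0.46 with fulvestrant added (0.35 to 0.61). B cell markers (0 of 14 past; 2 higher and 0 lower adjusted over the list alone, median 0.17, camera adjusted p = 0.0132) and markers of monocytes and interstitial macrophages (1 of 19, Cx3cr1; 1 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 0.0393) were higher, with adjusted p = 0.722 and 0.699 with an estimated correlation. The B cell mean relative to normoxia was -0.20 with fulvestrant added. The B cell call was lost without estradiol replicate 1 (0.0964) or 4 (0.153) or fulvestrant replicate 1 (0.092) or 2 (0.0622), and the monocyte call without estradiol replicate 2 (0.424) or 4 (0.151) or fulvestrant replicate 1 (0.132) or 3 (0.052).

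The other 4 of the 7 were called lower. They were cholesterol synthesis (0 of 19 past; 3 lower and 0 higher adjusted over the list alone, median log2 -0.19, camera adjusted p = 0.000687), epithelial junctions (0 of 18; 1 and 0, -0.13, 0.00277), fatty acid metabolism (0 of 21; 2 and 1, -0.12, 0.0139) and alveolar macrophage markers (1 of 16, Mrc1; 1 and 1, -0.21, 0.0247). With an estimated correlation the adjusted p was 0.694, 0.597, 0.694 and 0.694. Without estradiol replicate 3 the cholesterol (0.0957), fatty acid (0.0957) and alveolar macrophage (0.42) calls were lost, and the fatty acid call also without estradiol replicate 1 (0.0663).

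The 7 calls with fulvestrant were not stable: 0 without fulvestrant replicate 1 or 3, 2 without fulvestrant replicate 2, 3 without estradiol replicate 1, 1 without estradiol replicate 3, and 331 without estradiol replicate 4. All 7 genes lost the call in at least 1 of these fits: 6, 3, 6 and 0 of them without estradiol replicates 1 to 4 and 7, 6, 7 and 3 without fulvestrant replicates 1 to 4. All 7 kept their sign, which genes that passed in these same arrays could hardly fail to do. The largest move was 1.07-fold (Cx3cr1, to log2 0.81 without estradiol replicate 4), so the changes stayed of similar size. The share of higher genes was 42.9% and changed to 57.1% of 21 calls with median centring, 69.7% of 33 with quantile normalization again, 64.7% of 34 with an intensity trend and 57.1% of 77 without the dimmest genes.

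Opposite movement was counted directly. Of the 817 genes called in hypoxia, 672 (82.3%) had the opposite sign with estradiol. Nearly as many, 661 (80.9%), had the opposite sign with both drugs against hypoxia, where limma called 0 genes. Both comparisons use the hypoxia arrays that picked the 817, so these shares alone do not show a reversal by estradiol. Between hypoxia and estradiol, 45 genes were called in both with opposite signs against 3 called with the same sign. Independent sets of 817 and 112 genes with these numbers higher and lower would share 3.24 in opposite directions. Those with the largest changes were Or51e1, Lypd8l1, Grem1, Cxcl6 (log2 0.89 then -0.90), Prnd (1.13 then -0.85), Lypd1, Srpx (0.79 then -0.90), Il7r (-0.78 then 0.90), the adhesion gene Cdh13 (0.94 then -0.73) and Atp1b2 (0.67 then -0.71). All 112 genes called with estradiol had the opposite sign with fulvestrant, and 3 were called in both: Cx3cr1 (-0.74 then 0.72), Mrc1 (0.49 then -0.57) and Myo5b (0.28 then -0.46).

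Consecutive comparisons share a group, which by itself makes their fold changes run opposite. The correlation across genes, which are not independent replicates, was -0.44 between hypoxia and estradiol changes and -0.50 (SD 0.16) in 100 simulations of unchanged groups. It was -0.72 between estradiol and fulvestrant changes, against -0.49 (SD 0.17) in the simulations. The covariance, which is not scaled by the spread of the changes, was -0.0188 against -0.0080 (SD 0.0033) in the simulations for the first pair. For the second pair it was -0.0226 against -0.0081 (SD 0.0035). The 2 measures thus differ for the first pair. With the shared arrays divided into 2 and 2 the correlations were -0.24 (-0.35 to -0.14) and -0.30 (-0.43 to -0.20), for which no simulations were made. Over the 6 such splits the opposite calls had a median of 0 (0 to 9) in place of 45. In place of 3 they were 0 in every split. The splits also called fewer genes, with medians of 337.5 for hypoxia and 1 for estradiol in the first pair. In the second pair the medians were 9 for estradiol and 10 for fulvestrant. The 45 opposite calls were 4, 3 and 4 without hypoxia replicates 1, 2 and 4, 71, 3, 3 and 84 without estradiol replicates 1 to 4, and 27 without normoxia replicate 2. The 3 fulvestrant calls were 0, 0, 1 and 0 without hypoxia replicates 1 to 4, 1, 0, 0 and 169 without estradiol replicates 1 to 4, and 0, 1 and 0 without fulvestrant replicates 1 to 3. Both counts were 0 without estradiol replicates 2 and 3, and with normoxia replicate 4 counted as hypoxia.

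Against normoxia, hypoxia with estradiol gave 756 genes (417 higher and 339 lower, but 370 and 376 with median centring and 399 and 407 with quantile normalization again) and hypoxia with estradiol and fulvestrant gave 430 (286 higher, 144 lower). Ntrk2 was higher by 3.63 and 3.64 (log2), Slc26a10 by 1.94 and 2.07, and Bmp2 by 1.99 and 1.48. Cyp1a1 was lower at -3.34 and -3.87, and Lyve1 at -2.10 and -2.14. Grem1 was higher by 0.60 (adjusted p = 0.0226) and 1.09 (adjusted p = 0.000368), and Or51e1 differed by 0.60 (adjusted p = 0.275) with estradiol and 1.75 (adjusted p = 0.00184) with fulvestrant added. Of the 817 hypoxia calls, 322 were also called with estradiol and 315 with both drugs, all in the same direction. The normoxia arrays serve all 3 comparisons; with the normoxia arrays divided 2 and 2, so that none served both, the median counts were 110 and 126.5. The count for estradiol was 384 without normoxia replicate 1, 413 without normoxia replicate 2, 483 without estradiol replicate 3, and 325 without estradiol replicates 2 and 3. For both drugs it was 238 without normoxia replicate 1, 246 without fulvestrant replicate 3 and 258 without fulvestrant replicate 4. Hypoxia with both drugs against hypoxia gave 0 genes in limma (1009 at an unadjusted p under 0.05; 2 with array weights and 2 in a model of these groups alone), and in all 8 fits without 1 array.

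The hypoxia signature score averaged 0.067 ± 0.111 in normoxia, 0.633 ± 0.077 in hypoxia, 0.499 ± 0.039 with estradiol and 0.548 ± 0.024 with fulvestrant added (SD, n = 4). Estradiol minus hypoxia was -0.134 (exact permutation p = 0.0571, 0.0857 adjusted over 3 comparisons). Fulvestrant minus estradiol was 0.049 and fulvestrant minus hypoxia -0.085 (exact permutation p = 0.0857 each, 0.0857 adjusted). Estradiol minus hypoxia was -0.0822 without hypoxia replicate 1, and -0.158 without normoxia replicate 3 or hypoxia replicate 3 (exact permutation p = 0.0286 each). Fulvestrant minus estradiol was 0.0746 without estradiol replicate 1 (exact permutation p = 0.0286), 0.0325 without estradiol replicate 2 and 0.00869 without estradiol replicates 2 and 3. Fulvestrant minus hypoxia was -0.0423 without hypoxia replicate 1, and -0.112 and -0.106 without normoxia replicate 3 and hypoxia replicate 3 (exact permutation p = 0.0286 each). For the 200 higher genes alone, which include Ntrk2 and Grem1, fulvestrant minus estradiol was 0.113 (exact permutation p = 0.0286, the smallest possible; 0.114 adjusted). For the 200 lower genes it was 0.0155 (exact permutation p = 0.629), from a mean of -0.445 to -0.430, which is slightly further from the hypoxia mean of -0.561. Normoxia replicate 4, whose labels conflict, scored 0.089, the other normoxia arrays -0.069, 0.049 and 0.201, and the hypoxia arrays 0.539 to 0.729. The signature and normoxia mean behind its score were made without it. On the first principal component it lay at -19.7, and the hypoxia arrays lay at 1.44 to 16.3. These values argue against the hypoxia label for this array, so counting it as hypoxia probably mixes the groups. With replicate 4 counted as hypoxia, estradiol minus hypoxia became 0.054 (exact permutation p = 0.786).

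**Figure D4:**
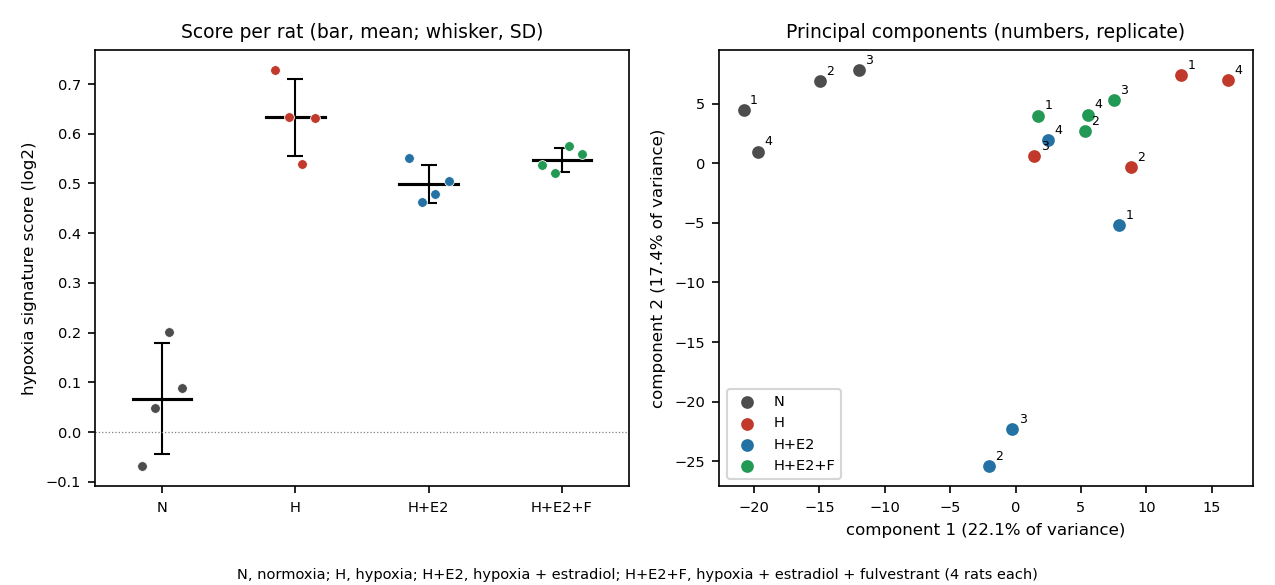
Left, hypoxia signature score (log2, vertical axis) in each rat by group, with mean bars and SD whiskers (n = 4), hypoxia at 0.633 and estradiol at 0.499 on average. Right, the first against the second principal component (22.1% and 17.4% of variance), with replicate numbers; estradiol replicates 2 and 3 lie at -25.4 and -22.3 on the second.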

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

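The tests of residual blood and of estradiol replicates 2 and 3 were chosen only after the neutrophil and clock results had been seen, and the number of simulations for the shared arrays was raised after their first results.

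For 120 named genes, 34 of the 47 gene lists (those whose results the text gives) and the signature score, 620 groups of 4 arrays were searched for 1 array far from the other 3 by Dixon's gap ratio. In 34 groups an array passed the 95% critical value for 4 samples, where chance alone gives about 1 in 20, or 31.0. The genes with a high array were Amd1 in normoxia replicate 4 (0.965), Gpx8 in normoxia replicate 3 (0.880), Rbp7 in hypoxia replicate 4 (0.852), and Plvap (0.952), Mfap5 (0.841) and Atp1b2 (0.920) in hypoxia replicate 1. Hopx was high in hypoxia replicate 3 (0.879), Retnlg (0.866) and Car4 (0.900) in estradiol replicate 2, Cx3cr1 in estradiol replicate 4 (0.845), Hmox1 in estradiol replicate 1 (0.834) and Ntrk2 in fulvestrant replicate 2 (0.986). The genes with a low array were Bnip3 in normoxia replicate 2 (0.837) and estradiol replicate 3 (0.922), Abcb1b (0.852) and Edn1 (0.875) in hypoxia replicate 4, and Cxcl12 in hypoxia replicate 2 (0.890). Gper1 was low in estradiol replicate 4 (0.839), Agt in estradiol replicate 2 (0.945), C1qa (0.858), Cdh13 (0.863) and Atp1b2 (0.918) in fulvestrant replicate 2, and Srpx (0.979) and Pou2af1 (0.907) in fulvestrant replicate 3.

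Among list means, erythrocyte markers were low in hypoxia replicate 3 (0.888) and high in fulvestrant replicate 2 (0.847). Glycolysis was high in estradiol replicate 1 (0.838), markers of monocytes and interstitial macrophages in normoxia replicate 3 (0.959), cardiac muscle markers in fulvestrant replicate 1 (0.940) and interferon genes in fulvestrant replicate 3 (0.830). Matrix genes were low in hypoxia replicate 4 (0.839) and B cell markers in hypoxia replicate 2 (0.914). Cholesterol synthesis was low in fulvestrant replicate 1 (0.853) and heat shock genes were high in hypoxia replicate 2 (0.885). Fulvestrant replicate 2 stood apart in 5 of the 34 groups and hypoxia replicate 4 in 4.

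Of the 13581 probe sets without a gene symbol, which no comparison of genes used, 336 passed for hypoxia against normoxia (126 higher and 210 lower) when all 29214 probe sets were tested, out of 972. Probe set 10857155 was 32.4-fold higher (log2 5.02, SE 0.28, adjusted p = 1.59e-07, n = 4), more than any named gene, and probe set 10859174 was 4.28-fold lower (log2 -2.10, SE 0.32, adjusted p = 0.0022). For estradiol against hypoxia 1 passed, probe set 10700622, 3.53-fold higher (log2 1.82, SE 0.22, adjusted p = 0.0176). These probe sets were singled out after their values were seen.

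The first pattern is the opposite movement of genes in consecutive comparisons. With the estradiol arrays divided 2 and 2, so that no array served both, 85.4% of the top 112 genes had opposite signs for estradiol and fulvestrant. In 1000 simulations of unchanged groups from permuted residuals, divided in the same way, the 95% range was 8.92% to 80.8%, and 9 were as high. The value was also above the range of the first 40 and 100 simulations. No array was shared in the simulations either, so they do not show what shared arrays give. They show that unchanged groups rarely gave so high a share. Permuting mixed the residuals of all groups, so the wider spread of the estradiol arrays (median SD 0.129) was not kept together. For hypoxia and estradiol the share among the top 817 genes was 71.0%, inside the range of 19.2% to 73.5% with 44 as high. It was above the range of the first 40 (27.0% to 68.9%). That opposite movement was thus not shown to go beyond unchanged groups, and shared hypoxia arrays were not excluded as its cause. An action of estradiol through its receptors, which the design names, stays open for both.

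The second pattern is the higher neutrophil list with estradiol. Residual blood would raise erythrocyte and platelet markers as well. The neutrophil mean rose by 0.82 (exact permutation p = 0.0286), the erythrocyte mean shifted by -0.47 (exact permutation p = 0.286) and the platelet mean by 0.05 (exact permutation p = 0.686). The difference was 1.03 (exact permutation p = 0.0286). The platelet mean thus gave no sign of more blood. Erythrocyte markers are a poor gauge, since their mean in hypoxia was already 0.97 above normoxia, with hypoxia replicate 3 at -0.06. Their fall also adds to the 1.03. The neutrophil list was picked after its rise was seen, so its p, the smallest possible, adds little. Residual blood is therefore not excluded. Estradiol replicates 2 and 3 carry the highest neutrophil values, but without them the neutrophil shift was 0.53, with replicates 1 (0.42) and 4 (0.29) above the highest hypoxia array (0.08) and the list still called (median 0.47, camera adjusted p = 3.36e-07, but adjusted p = 0.779 with an estimated correlation). More neutrophils in the lung or in the blood may explain it, but neither was measured, and handling or batch, which follow the groups, stay open.

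The third pattern is the higher clock list with estradiol. Sampling at another time of day would lower Bmal1, Npas2 and Clock while the Per genes rise; their mean shifted by -0.53 (exact permutation p = 0.0571), with these values for single genes, of which all but Per1 lie outside the rule for named genes and are given for this test: Bmal1 at -0.80, Npas2 at -0.62, Clock at -0.17, Per1 at 1.31, Per2 at 1.01, Per3 at 0.78 and Dbp at 0.77. Other clock genes outside the rule shifted less and did not pass. Among them were Nr1d2 at 0.50, Nr1d1 at 0.37 (SE 0.74), Tef at 0.36, Nfil3 at 0.35, Cry2 at 0.25 and Cry1 at 0.18. Without estradiol replicates 2 and 3 the list shifted by 0.25 and stayed called (camera adjusted p = 0.0208, but adjusted p = 0.779 with an estimated correlation), but replicate 4 (0.04) lay below the highest hypoxia array (0.37). Time of day and an effect of estradiol cannot be told apart, since no sampling time is given and the p is just above 0.05. A stress response may add to it, as the glucocorticoid list was also higher (median 0.17, camera adjusted p = 0.0208 without replicates 2 and 3), though this call too was lost with an estimated correlation (adjusted p = 0.779).

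For the numbers of genes called in 5 comparisons, no other split of the same arrays gave as many. This speaks against chance but does not exclude it. A share of 1 of 35 is the least such a test can give, and the comparisons were not adjusted for their number. Splits that mix different groups also have a wider spread within groups, which lowers their counts. For hypoxia against normoxia (817 genes; highest other split 0), estradiol against hypoxia (112; 7), fulvestrant against estradiol (7; 1), estradiol against normoxia (756; 4) and both drugs against normoxia (430; 0), 1 of 35 splits was as large, the real one. The opposite calls add no evidence of their own, although 1 of 70 assignments was as large for both (45 with a highest other of 30, and 3 with a highest other of 0). Assignments with few called genes cannot hold many opposite calls, and the 30 came from exchanging the hypoxia and estradiol labels as a whole. Chance cannot be excluded for the numbers of lists. In hypoxia 18 were called, with 7 of 35 splits as large (median of the others 15.5, highest 22). With estradiol 15 were called, with 17 of 35 splits as large (14 and 28). With fulvestrant 18 were called, with 9 of 35 splits as large (14 and 20). Other groupings of the same arrays thus typically called nearly as many lists. For both drugs against hypoxia the real count was 0 in limma (1009 at an unadjusted p under 0.05, 2 with array weights and 2 in a model of these groups alone), so 35 of 35 splits had to be as large (highest other 1) and the splits say nothing about chance.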

How the results depend on the processing

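Leaving out estradiol replicates 2 and 3 together was chosen only after the data were seen. Averaging a gene's probe sets kept every count of called genes within 1.5 times, and no named gene that passed reversed its sign under any alternative. The alternatives reuse the arrays in which these genes passed, so a reversal was hardly possible. For fulvestrant against estradiol the count was 21 with median centring, 33 with quantile normalization again, 77 without the dimmest genes, where fewer genes are tested, and 34 with an intensity trend; its opposite calls were then 11, 15, 36 and 15, and those of hypoxia and estradiol were 74 without the dimmest genes. With all probe sets estradiol against hypoxia gave 4 genes, fulvestrant against estradiol 1, and the opposite calls were 4 and 0. With array weights these were 4 genes for estradiol against hypoxia, 786 for both drugs against normoxia, 2 for both drugs against hypoxia, and 3 and 0 opposite calls. Without moderation they were 1 for estradiol, 1 for fulvestrant, 475 for estradiol against normoxia, and 1 and 0 opposite calls. In models of the compared groups alone they were 5 for estradiol, 0 for fulvestrant in limma (2142 at an unadjusted p under 0.05 in the 4-group model), 216 for estradiol against normoxia, 2 for both drugs against hypoxia, and 3 and 0 opposite calls. At an adjusted p under 0.10 the counts were 1382 for hypoxia, 366 for estradiol, 242 for fulvestrant, 1153 for estradiol against normoxia, 690 for both drugs against normoxia, and 143 and 102 opposite calls. With at least 1.5-fold they were 280, 44, 1, 251 and 151, and 11 and 1 opposite calls. With normoxia replicate 4 counted as hypoxia they were 40 for hypoxia, 0 for estradiol, 351 for estradiol against normoxia and 100 for both drugs against normoxia, with 0 and 0 opposite calls and 9 lists for estradiol. The score differences then reversed, estradiol minus hypoxia to 0.0536 (exact permutation p = 0.786) and both drugs minus hypoxia to 0.0577 (exact permutation p = 0.81); an array with a score of 0.089 then lowers the hypoxia mean. Of the lists called in hypoxia, mitosis (adjusted p = 0.223), DNA replication (0.404), cholesterol synthesis (0.153), vascular tone (0.135) and markers of monocytes and interstitial macrophages (0.218) lost the call in this setting. So did, with estradiol, the endothelial (0.0985), erythrocyte (0.135), interferon (0.246), natural killer (0.123), pericyte (0.0818), vascular tone (0.0512) and T cell (0.246) lists. Without the dimmest genes the hypoxia calls of alveolar type 1 (0.0908), DNA replication (0.102), capillary (0.076), monocyte (0.0555) and vascular tone (0.0908) lists and the estradiol calls of actin filament (0.0953), erythrocyte (0.0684) and heat shock (0.0616) lists were lost. With quantile normalization again alveolar type 1 (0.0619) and capillary (0.0602) markers in hypoxia and actin filament genes with estradiol (0.0754) lost theirs, and averaging probe sets ended those of vascular tone in hypoxia (0.0647) and actin filament genes with estradiol (0.0657). With fulvestrant the alveolar macrophage call ended without the dimmest genes (0.104) and without estradiol replicates 2 and 3 (0.310), the monocyte call without the dimmest genes (0.0655) and the cholesterol synthesis call without estradiol replicates 2 and 3 (0.352). With an estimated correlation 0, 0 and 0 lists were called, and with fry 12, 0 and 0. Without estradiol replicates 2 and 3 the counts were 0 for estradiol, 0 for fulvestrant (1335 and 1329 at an unadjusted p under 0.05) and 325 for estradiol against normoxia, with 0 and 0 opposite calls, and fulvestrant minus estradiol in score was 0.00869 (exact permutation p = 0.6). Other than where construction is named, the cause was not tested.

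Leaving out 1 array at a time gave 428 to 986 genes for hypoxia, 3 to 355 for estradiol, 0 to 331 for fulvestrant, 384 to 887 for estradiol against normoxia, 238 to 374 for both drugs against normoxia and 0 to 0 for both drugs against hypoxia. Lists called ranged from 16 to 20, 11 to 22 and 15 to 18, and opposite calls from 3 to 84 and 0 to 169. Score differences ranged from -0.158 to -0.082, 0.032 to 0.075 and -0.112 to -0.042 for estradiol minus hypoxia, fulvestrant minus estradiol and fulvestrant minus hypoxia. Signal over background could not be assessed, since RMA values carry no background level.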

Other observations

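The lists in this part were singled out only after their results were seen, and the test of the aryl hydrocarbon receptor was set before its result was seen.

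Cyp1a1 was 23.0-fold lower in hypoxia, and lower activity of the aryl hydrocarbon receptor may be the cause. Of 5 other genes that receptor induces, 4 were measured, and their mean shifted by -0.0535 (exact permutation p = 0.657), with these single genes, named for this test and outside the rule for named genes: Cyp1a2 at 0.04, Cyp1b1 at -0.05, Ahrr at 0.06 and Nqo1 at -0.26. A general loss of receptor activity was not shown, and a change at Cyp1a1 itself stays untested.

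Cardiac muscle markers (22 genes) were not called in hypoxia (median -0.31, camera adjusted p = 0.104), with 0 passing. Their list mean relative to normoxia was -0.78, -0.76, 0.26 and 1.29 in normoxia replicates 1 to 4, and between -0.63 and -0.18 in the other 12 arrays. Erythrocyte markers were above the normoxia mean by 0.50 ± 0.55 with estradiol and 0.81 ± 0.41 with fulvestrant added (SD, n = 4).

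Besides mitosis, lists with 0 passing genes that camera called higher in hypoxia were DNA replication (29 genes, median 0.20, adjusted p = 0.0149, and adjusted p = 0.824 with an estimated correlation) and cholesterol synthesis (19 genes, median 0.23, adjusted p = 0.0344, and adjusted p = 0.824 with an estimated correlation). DNA replication lost the call without normoxia replicate 4 (0.107) or hypoxia replicate 4 (0.255), and cholesterol synthesis without normoxia replicate 1 (0.188) or 4 (0.0765) or hypoxia replicate 4 (0.363). The interferon list was lower with estradiol (29 genes, 0 passing, median -0.27, adjusted p = 0.00716, and adjusted p = 0.819 with an estimated correlation), a call lost without estradiol replicate 3 (0.355). Without estradiol replicates 2 and 3 its median was 0.0052 (camera adjusted p = 0.527), so no lower shift was left.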
